A study of Homo sapiens with 6 samples.

How the data were processed

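Gene expression was measured in MCF-7 cells, an estrogen receptor positive human breast cancer line, on 6 Affymetrix arrays of 1 colour. Per the labels, 3 arrays held RNA from control cells and 3 held RNA from cells given Delta-2-TGZ at 25 µM, both collected at 12 h. Delta-2-TGZ is delta-2-troglitazone, a derivative of the thiazolidinedione troglitazone that the series title describes as inactive on PPARγ. The source label of the control cells says that they received no treatment, whereas the treatment protocol names DMSO, the solvent, as the alternative to the compound. The control is therefore called the control here, and whether it received solvent stays unsettled. Per the labels' protocols, cells were grown in DMEM in plates with 6 wells, total RNA was extracted on columns, and 250 ng of it was turned into biotin-labelled cDNA with a whole-transcript kit. The titles call the arrays biological replicates, without saying whether the cultures were separate in time, so p-values measure the spread between these arrays, which may be partly technical.

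The deposited values are log2 values, 1 per probe set and array, and the submitters' processing notes name GCOS, Affymetrix Expression Console 1.1 and RMA, with no role or order given. RMA subtracts background, makes the distributions of probe intensities equal between arrays and summarises the probes of each probe set on the log2 scale, so a shift shared by all transcripts would be removed and large differences are compressed. The settings, the genome build and the annotation used by the authors are not given in the sources used here. The table held 33297 probe sets with no missing value, and the array medians lay between 6.54 and 6.63 on the log2 scale. No scanner intensities or detection calls were used here, so a low value cannot be separated from background. The number of arrays limits the precision.

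Probe sets were named through the GEO annotation of the array platform. It gave 1 gene for 19460 probe sets, several genes for 1754 and none for 12083. The last are unnamed here, and whether they represent genes is not known from the sources used. Of the probe sets with 1 gene, 19429 had an identifier in a RefSeq table of the assembly GRCh38.p14, used for names alone, and 0 symbols needed an update. Each of 18417 genes was represented by its probe set with the highest mean over the 6 arrays, and 769 genes had more than 1 probe set. Probe sets with several genes or none entered no test of genes.

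Delta-2-TGZ was compared with control by limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited log2 values, the group as the only term and Benjamini-Hochberg adjustment over all genes. A gene was called changed at an adjusted p under 0.05, and a second count also required a fold change of at least 1.5. Changes are Delta-2-TGZ minus control, errors of changes are standard errors of that fit, and adjusted p-values are two-sided. For 29 gene lists with 890 members, of which 812 entries and 793 different genes were measured, the members called over all genes and those called when adjusted over the list alone were counted. A shift of each list against all other genes was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 29 lists. Where the text says "with an estimated correlation", camera estimated that correlation for each list from the residuals. In that setting it also judges its statistic by the residual degrees of freedom, here 4, rather than by the number of genes. Its p-values can therefore be higher even where the estimated correlation is low.

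The comparison, the lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the 12 largest increases and the 12 largest decreases among called genes whose 3 treated values all lay above or all below the control values. It also took up to 4 called members of each list by size of change, or the member with the largest change where none was called. ESR1, CCND1, EGR1, PPARG, DDIT3, HSPA5, ATF3, CDKN1A, GAPDH and ACTB were always taken, and the text may name fewer genes in that order. Members outside this rule are named where 5 or fewer members of a list were called in a direction, and these, like the gene families of the last part, were chosen after their values were seen.

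The procedure was tested on simulated data with the same 18417 genes, of which 67, 67 and 66 were changed 1.5-fold, 2-fold and 4-fold. It recovered 73.1% of the genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold. Of 194 calls, 13 were false, or 6.7%. In the simulation with 1 shifted list, that list was called and 0 of 23 lists without shifted genes were. The simulated genes varied independently, whereas the estimated correlation reached 0.926 in the mitosis list and 0.916 in the interferon list. The simulation therefore does not test list calls where members vary together.

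Alternatives set the array medians equal, applied quantile normalization again, left out genes at or below the 30th percentile of all probe sets, used an intensity trend with robust variances, used array weights, or added the replicate number as a block. Others averaged the probe sets of a gene, tested all probe sets, left out each array in turn, lowered the adjusted p to 0.01, raised the fold to 2, tested against a fold of 1.2 with limma's treat, or replaced camera by camera on ranks or by fry. Fry tests whether the members of a list move, on balance, 1 way against no change, and does not compare them with other genes. Leaving out both arrays numbered 3, and leaving out genes with identical values on 2 or 3 arrays of a group, were added after the data were seen. Such ties were found in 3262 genes, whose variance estimates can be too small. Of these, 60 were called, or 1.84%, against 23.2% of the other genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.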

Results

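The series measured mRNA levels in MCF-7 cells after 12 h with Delta-2-TGZ at 25 µM or without it, on 3 Affymetrix arrays per group. The median log2 value was 6.58, 6.54 and 6.56 on the control arrays and between 6.57 and 6.63 on the Delta-2-TGZ arrays, and the number of arrays limits the precision. The series addressed how a troglitazone derivative described as inactive on the nuclear receptor PPARγ affects gene expression in a breast cancer line. The arrays of a group correlated at 0.9897 to 0.9965 over genes, and arrays of different groups at 0.9749 to 0.9835. The first principal component held 70.5% of the variance and separated the groups. The second held 15.2% and spread the treated arrays, from 19.7 for Delta-2-TGZ replicate 1 to -21.6 for Delta-2-TGZ replicate 3. GAPDH and ACTB, which are commonly used reference genes, differed by -0.07 ± 0.06 (SE, adjusted p = 0.463) and -0.03 ± 0.07 (adjusted p = 0.825) on the log2 scale. The sign of the GAPDH difference turned after quantile normalization again (0.01). The ACTB difference ranged from -0.076 to 0.011 over the fits without 1 array. Where 5 or fewer members of 1 of the 29 gene lists rose or fell, these are named, and those outside the rule for named genes were chosen after their values were seen.

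Delta-2-TGZ raised 31 of 36 measured targets of the stress factors ATF4 and CHOP and lowered 36 of 42 genes of the G1/S transition and DNA replication, the latter with an adjusted p = 0.165 as a list with an estimated correlation. SLC7A11, the transport subunit of the cystine-glutamate exchanger, rose 18.1-fold (log2 change 4.17 ± 0.14 SE, n = 3 per group, limma adjusted p = 6.69e-05). DDIT3, which encodes the stress transcription factor CHOP, rose 13.8-fold (3.78 ± 0.27, adjusted p = 0.00054). CCNE2, which encodes cyclin E2 of S phase entry, fell 6.12-fold (-2.61 ± 0.14, adjusted p = 0.000223). SLC7A11 and DDIT3 were read from probe sets 8102800 and 7964460.

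The largest increase was that of CLDN1, a tight junction protein, which went from 7.41 ± 0.47 (SD, n = 3) in control to 11.67 ± 0.29 with Delta-2-TGZ, or 19.2-fold. MAP1B, a microtubule-associated protein, rose 18.4-fold, and HMOX1, heme oxygenase 1, rose 13.7-fold from 7.60 ± 0.16 to 11.37 ± 0.41 (SD). HBEGF, a ligand of the EGF receptor, rose 12.9-fold and the ETS family factor ETV5 12.8-fold. IL18, a cytokine, rose 12.5-fold from a low control level of 4.75 ± 0.43 (SD), not separated from background, so that this fold is uncertain, and ANXA1, annexin A1, rose 11.6-fold. ULBP1, a ligand of the natural killer receptor NKG2D, rose 9.94-fold. CCNA1, cyclin A1, and B3GNT5, a glycosyltransferase, rose by 3.46 and 3.17 on the log2 scale. The control levels of CCNA1, ETV5 and B3GNT5 were 5.75, 5.95 and 6.26, below the array medians. Their folds carry the same limit as that of IL18. The adjusted p of the 12 genes with the largest increases ranged from 3.56e-05 for ULBP1 to 0.00134 for IL18.

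Of the genes that fell, TNFSF10, the death ligand TRAIL, had the largest decrease by the probe set used for each gene, 9.14-fold (-3.19 ± 0.45 SE, adjusted p = 0.00461). Its controls differed, with an SD of 0.85, and lay at 8.51, 9.03 and 10.18 on control replicates 1, 2 and 3. The TNFSF10 change ranged from -3.555 to -2.721 over the fits without 1 array, so its rank depends on the arrays used. FAM111B fell 7.87-fold, PPP1R3C, a glycogen-targeting subunit of protein phosphatase 1, 7.58-fold, HCAR1, the lactate receptor, 7.21-fold and MSMB 6.63-fold. HCAR1 and PPP1R3C fell to low levels of 5.12 and 5.57, not separated from background, so that their folds are uncertain. SYNPO2, TMEM164 and MMP16 fell 5.92-fold, 5.85-fold and 5.22-fold. MMP16 had a second probe set of slightly lower mean level with a log2 change of -3.57, larger than that of TNFSF10. SFXN2 fell 5.17-fold, GPER1, a membrane estrogen receptor, 5.14-fold and the cadherin CDH18 4.93-fold. The treated levels of MSMB, TNFSF10 and CDH18 were 5.78, 6.05 and 6.08, below the array medians. Their folds carry the same limit as that of HCAR1. The calls of all 24 genes with the largest changes held in each fit without 1 array.

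**Figure D1:**
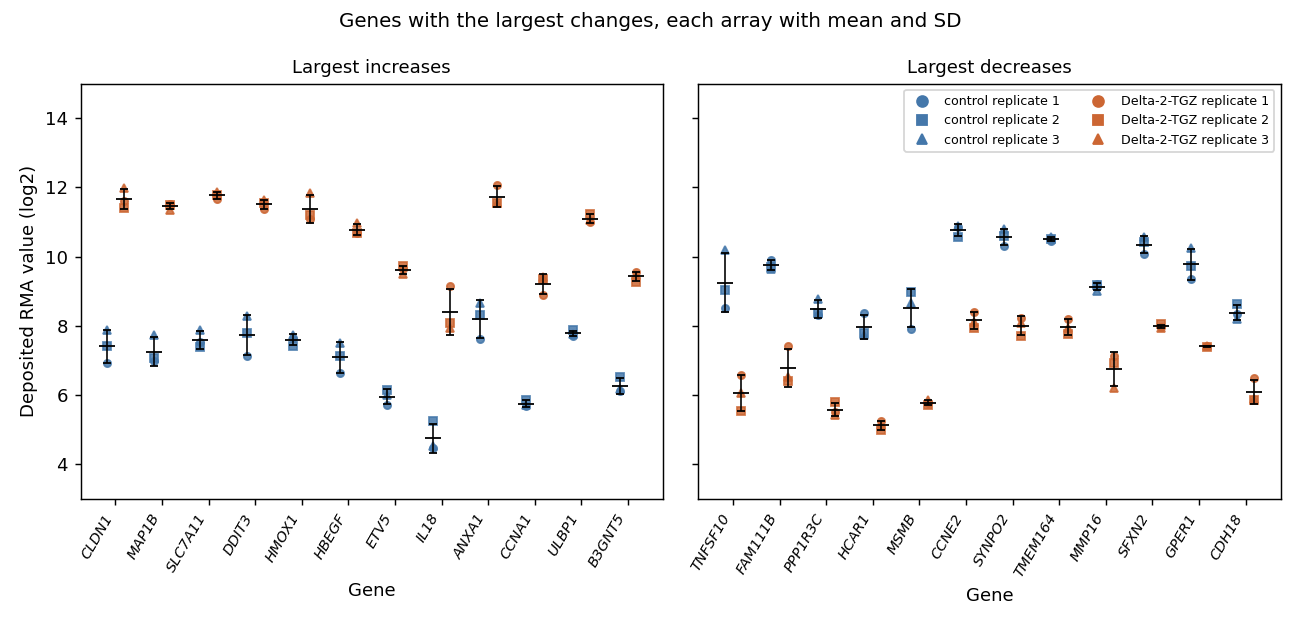
Deposited RMA values (log2, vertical axis) of the 12 genes with the largest increases (left) and the 12 with the largest decreases (right), with a symbol for each array, control in blue and Delta-2-TGZ in orange, and black bars for mean and SD (n = 3). The treated values of CLDN1 lie around 11.67 against 7.41 in control, and those of TNFSF10 around 6.05 against 9.24.

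In all, 3580 of 18417 genes changed, or 19.4%, of which 1769 rose and 1811 fell. All 3580 had treated values that lay entirely above or below the controls, as did 35.1% of all genes, against 10% by chance for 3 against 3. At a fold of at least 1.5, 935 genes rose and 841 fell, together 1776. At least 2-fold, 346 rose and 262 fell, and at least 8-fold, 14 rose and 1, TNFSF10, fell, by the probe set used for each gene. The TNFSF10 decrease did not reach 8-fold in each fit without 1 array (log2 change up to -2.721). The count of changed genes moved by over 1.5 times with array weights (5981), at an adjusted p under 0.01 (1669), without both arrays numbered 3 (1678), and without control replicate 1 (2255), 2 (2322) or 3 (2245) or Delta-2-TGZ replicate 2 (2267). The 1.5-fold count did so only when the fold was raised to 2 (608). Of 175 genes followed over the alternatives, 56 lost their call without both arrays numbered 3. Of genes named in this Results part whose calls held in each fit without 1 array, these were HMGCS1, H2BC3, EGLN3, COX7B, RRP12, NHP2, CDKN1A, BAG3, MYC, KRT7 and KDM3A (adjusted p between 0.0548 and 0.0933).

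Across the 29 gene lists, 10 shifted up and 9 down by camera with the preset correlation, and 4 of these 19 calls held with an estimated correlation. These 4 were the ATF4 and CHOP targets, the tRNA synthetases, the XBP1 targets and the immediate early genes, and all 4 were up.

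**Figure D2:**
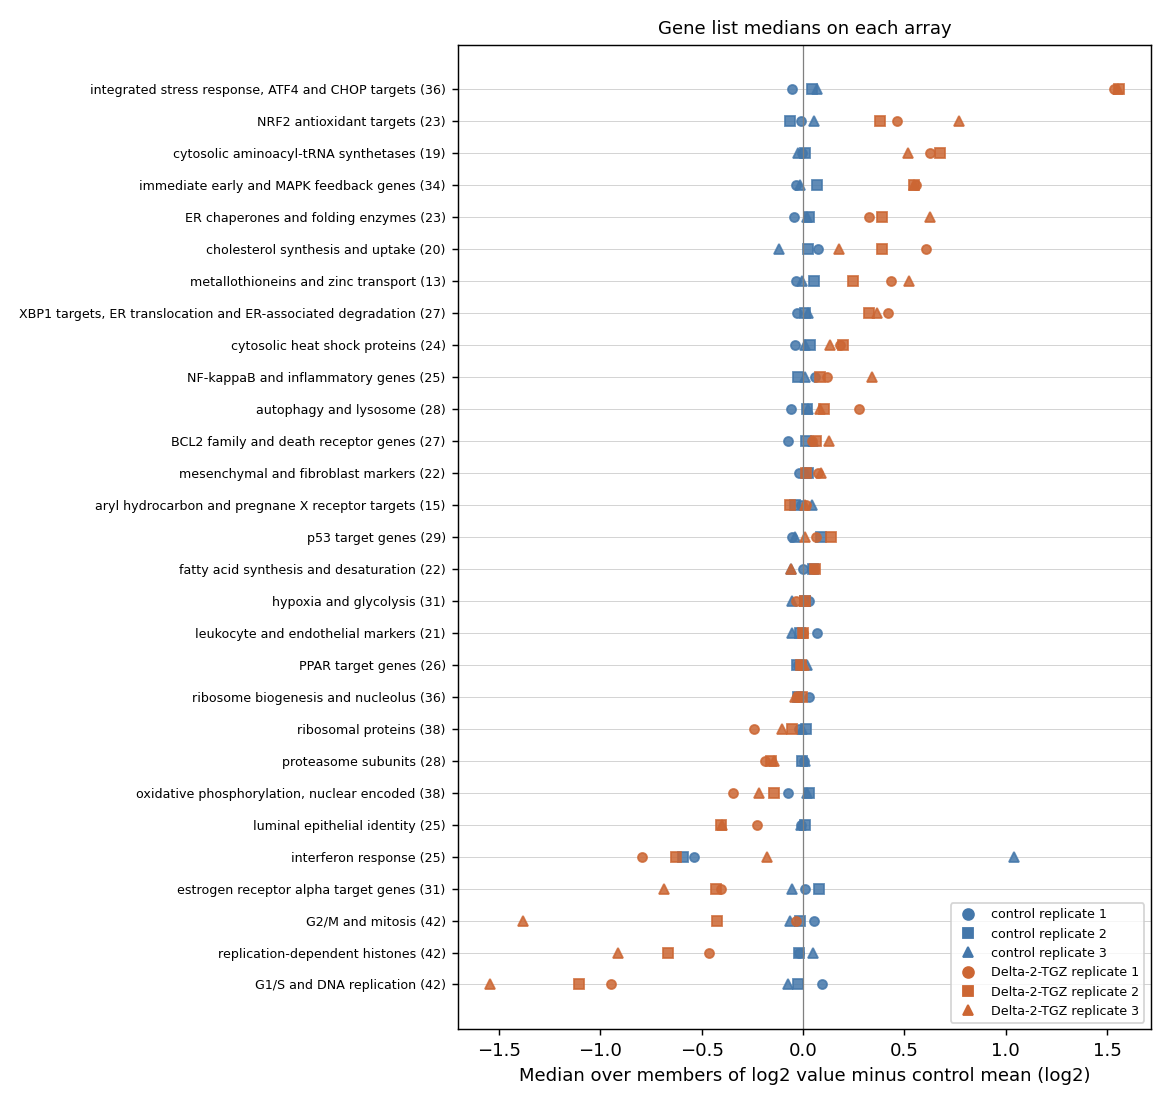
Median over the measured members (their number in brackets) of each gene list, as log2 value minus the gene's control mean, on each of the 6 arrays, control in blue and Delta-2-TGZ in orange. The ATF4 and CHOP list lies at 1.54, 1.56 and 1.55 on the treated arrays, the G1/S list at -0.95, -1.10 and -1.54, and control replicate 3 lies apart at 1.04 for the interferon list.

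The integrated stress response list, targets of the transcription factors ATF4 and CHOP, moved furthest. Of its 36 measured members 31 rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 1.57 (camera adjusted p = 4.16e-25, and adjusted p = 0.0353 with an estimated correlation). After SLC7A11 and DDIT3, its largest increases were those of CHAC1, a glutathione-degrading enzyme, at 8.16-fold (3.03 ± 0.07 SE, adjusted p = 3.56e-05) and ALDH1L2, of mitochondrial folate metabolism, at 7.23-fold from 4.79 ± 0.03 (SD). That ALDH1L2 level is not separated from background and 2 of its control values are identical, so its fold is uncertain and its SD can be too small. ATF3 rose 3.66-fold (adjusted p = 0.00054). The list shares 7 genes with other lists. Of 19 cytosolic aminoacyl-tRNA synthetases 12 rose and 1 fell, or 13 and 2 adjusted over the list alone (median 0.59, adjusted p = 3.75e-07, and adjusted p = 0.0495 with an estimated correlation). YARS1, SARS1, WARS1 and GARS1, the enzymes for tyrosine, serine, tryptophan and glycine, rose 2.39-fold, 2.33-fold, 2.32-fold and 2.15-fold. The member that fell was QARS1, for glutamine (-0.39 ± 0.10 SE), whose call was lost in each fit without 1 array (adjusted p up to 0.101).

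Of 23 chaperones and folding enzymes of the endoplasmic reticulum 12 rose and 0 fell, or 14 and 0 adjusted over the list alone (median 0.49, adjusted p = 2.49e-08, but adjusted p = 0.129 with an estimated correlation). DNAJB9, a co-chaperone, rose 5.59-fold, HERPUD1 3.24-fold, HSPA13 2.34-fold and HSPA5, which encodes the chaperone BiP, 2.33-fold (1.22 ± 0.09 SE, adjusted p = 0.000515). Of 27 genes for XBP1 targets, translocation and degradation 16 rose and 0 fell, or 18 and 0 adjusted over the list alone (median 0.37, adjusted p = 9.53e-09, and adjusted p = 0.0495 with an estimated correlation). Beside DNAJB9, a member of both lists, ERN1, which encodes the stress sensor IRE1, rose 3.47-fold and UFM1, a ubiquitin-like modifier, 2.40-fold. The cytosolic heat shock list had 24 measured members, of which 9 rose and 2 fell, also when adjusted over the list alone (median 0.20, adjusted p = 0.00157, but adjusted p = 0.106 with an estimated correlation). The HSP40 co-chaperones DNAJB4, DNAJA4 and DNAJB1 rose 2.48-fold, 2.05-fold and 1.87-fold. BAG3 and FKBP4 fell, by 0.61 and 0.44 on the log2 scale, FKBP4 with a call lost without any control array or without Delta-2-TGZ replicate 3 (adjusted p up to 0.0964), and both with calls lost without both arrays numbered 3 (adjusted p = 0.0933 and 0.157). The proteasome list moved the other way, with 7 of 28 subunits lower and 0 higher, or 8 and 0 adjusted over the list alone (median -0.16, adjusted p = 0.00123, but adjusted p = 0.0937 with an estimated correlation). PSMD3 fell 1.59-fold and PSMA5 1.33-fold.

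Of 23 targets of the antioxidant factor NRF2, 12 rose and 0 fell, or 13 and 1 adjusted over the list alone (median 0.67, adjusted p = 0.000536, but adjusted p = 0.457 with an estimated correlation). After SLC7A11 and HMOX1, the transporter gene ABCC3 rose 3.32-fold and GCLM, a subunit of the enzyme that makes glutathione's precursor, 2.35-fold. The metallothionein and zinc transport list had 6 of 13 members higher and 1 lower, or 9 and 2 adjusted over the list alone (median 0.40, adjusted p = 0.00401, but adjusted p = 0.457 with an estimated correlation). MT1F rose 2.47-fold and MT1X 1.87-fold, and metallothionein probe sets can share signal between near-identical copies. The member that fell was the zinc importer SLC39A10 (-0.63 ± 0.15 SE), whose call was lost without any control array or without Delta-2-TGZ replicate 3 (adjusted p up to 0.0973).

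Of 34 immediate early and MAPK feedback genes, which growth factor signalling induces, 21 rose and 0 fell, or 26 and 0 adjusted over the list alone (median 0.56, adjusted p = 3.02e-15, and adjusted p = 0.0495 with an estimated correlation). After ETV5, EGR1, an early growth response factor, rose 6.51-fold from 9.04 ± 0.11 to 11.74 ± 0.18 (SD). SPRY4, an inhibitor of the pathway, rose 4.44-fold and PHLDA1 4.41-fold. Of 25 NF-kappaB and inflammatory genes 7 rose and 0 fell, also when adjusted over the list alone (median 0.15, adjusted p = 0.0158, but adjusted p = 0.457 with an estimated correlation and adjusted p = 0.0748 with array weights). The cytokine IL6 rose 4.57-fold from a low level of 5.10 ± 0.11 (SD), not separated from background, so that this fold is uncertain. LIF rose 3.34-fold and the adhesion molecule ICAM1 2.74-fold.

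Genes of DNA replication fell together. Of 42 G1/S members 36 fell and 0 rose, or 39 and 0 adjusted over the list alone, with a median log2 change of -1.19 (adjusted p = 4.16e-25, but adjusted p = 0.165 with an estimated correlation). Beside CCNE2, the helicase subunits MCM2 and MCM3 fell 4.69-fold (-2.23 ± 0.08 SE, adjusted p = 9.51e-05) and 4.27-fold. UHRF1, of DNA methylation upkeep, fell 4.24-fold, while its second probe set, with a mean of 6.03, moved by 0.09. Of 42 replication-dependent histone genes 26 fell and 0 rose, or 35 and 0 adjusted over the list alone (median -0.67, adjusted p = 6.32e-15, but adjusted p = 0.249 with an estimated correlation). H2AC4 fell 4.31-fold and H2BC3 4.08-fold, and histone probe sets can share signal between near-identical copies.

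Mitosis genes were less even between the treated arrays. Of 42 G2/M members 7 fell and 1 rose, also when adjusted over the list alone, with a median of -0.59 (adjusted p = 8.56e-06, but adjusted p = 0.559 with an estimated correlation and adjusted p = 0.239 by fry). The list median lay at -0.03, -0.42 and -1.38 on Delta-2-TGZ replicates 1, 2 and 3, while the controls lay between -0.06 and 0.06. Without Delta-2-TGZ replicate 3 the median was -0.23, with 8 members lower, and without Delta-2-TGZ replicate 1 it was -0.96, with 19 lower. Without Delta-2-TGZ replicate 2 or control replicate 1 or 3, 1 member was lower, and without control replicate 2, 3 were. KIF11, a motor protein of the spindle, fell 2.68-fold (adjusted p = 0.0336), but this call was lost without any control array or without Delta-2-TGZ replicate 2 (adjusted p up to 0.118). The member that rose was the phosphatase CDC25B (0.51 ± 0.07 SE, adjusted p = 0.00462). CCND1, cyclin D1, did not pass the threshold (-0.22 ± 0.12 SE, adjusted p = 0.271), and its change ranged from -0.295 to -0.095 over the fits without 1 array. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 2.71-fold (adjusted p = 0.00444), a call lost without both arrays numbered 3 (adjusted p = 0.0649).

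**Figure D3:**
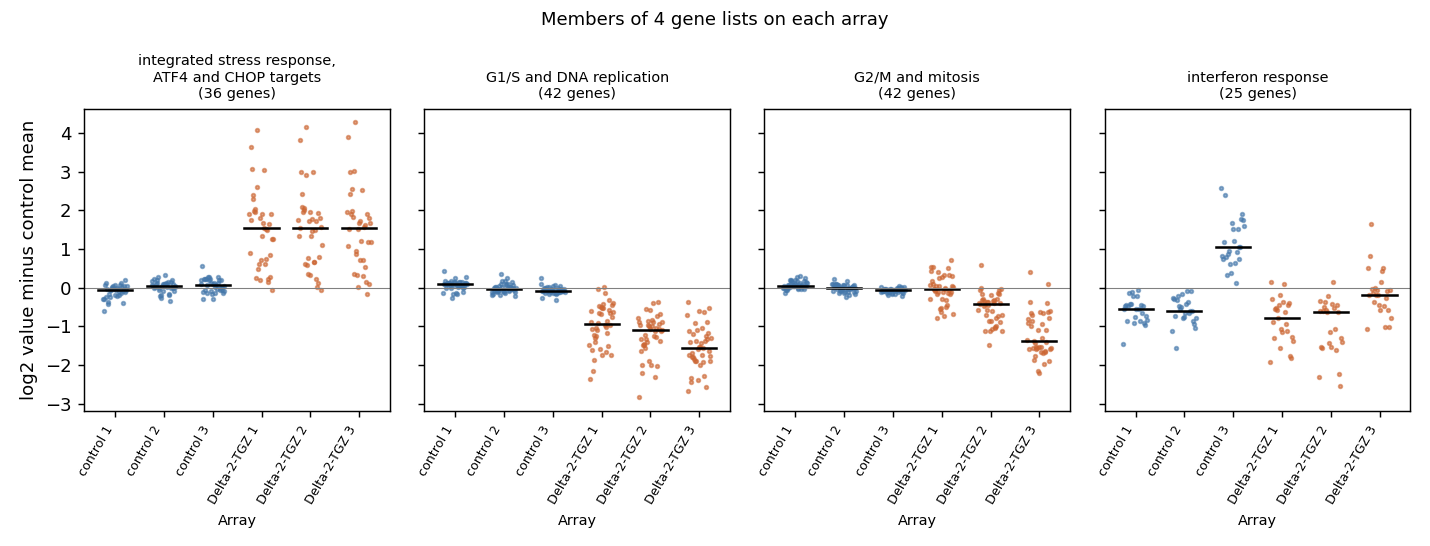
Each point is a member of 1 of 4 gene lists, as log2 value minus the gene's control mean (vertical axis), on each of the 6 arrays, and black bars are medians. The ATF4 and CHOP members sit alike on the treated arrays (medians 1.54, 1.56 and 1.55), the mitosis members spread between them (-0.03, -0.42 and -1.38), and the interferon members are high on control replicate 3 (1.04).

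ESR1, which encodes estrogen receptor alpha, fell 2.44-fold from 10.99 ± 0.11 to 9.70 ± 0.74 (SD, adjusted p = 0.0421). It lay at 10.23, 10.02 and 8.85 on Delta-2-TGZ replicates 1, 2 and 3, and the log2 change was -0.86 without Delta-2-TGZ replicate 3. This call was close to the threshold: it was lost without any control array or without Delta-2-TGZ replicate 2 (adjusted p between 0.00662 and 0.128 over the fits without 1 array), and when its dim second probe set, which moved by 0.14, was averaged in (adjusted p = 0.118). Of 31 target genes of the receptor 17 fell and 3 rose, or 20 and 4 adjusted over the list alone (median -0.50, adjusted p = 5.32e-07, but adjusted p = 0.273 with an estimated correlation). GREB1 and MYB were also lowest on Delta-2-TGZ replicate 3, GREB1 at 7.84 against 9.24 and 9.14 on the other treated arrays. GREB1 fell 4.11-fold, with a call lost without control replicate 1 or 2 (adjusted p up to 0.0596), the carbonic anhydrase CA12 4.08-fold (-2.03 ± 0.12 SE) and MYB 3.75-fold. The members that rose were FHL2 (1.09 ± 0.19 SE), MYC (0.56 ± 0.08 SE) and IGF1R (0.38 ± 0.07 SE), the last with a call lost when probe sets were averaged (adjusted p = 0.213). Of 25 luminal epithelial genes 12 fell and 2 rose, or 15 and 2 adjusted over the list alone (median -0.24, adjusted p = 8.56e-06, but adjusted p = 0.0937 with an estimated correlation). After ESR1, SPDEF, an epithelial transcription factor, fell 2.36-fold (-1.24 ± 0.12 SE). KRT7 and CLDN7 rose by 0.32 ± 0.06 and 0.25 ± 0.06 (SE), CLDN7 with a call lost after median centring (adjusted p = 0.0688) and without any 1 array except Delta-2-TGZ replicate 1 (adjusted p up to 0.0958).

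PPARG, the gene for PPARγ, rose 2.39-fold from 8.27 ± 0.40 to 9.53 ± 0.29 (SD, adjusted p = 0.0109), a call lost without control replicate 1 (adjusted p = 0.0514). The list of 26 PPAR targets did not shift (median -0.01, mean 0.04, camera direction down, adjusted p = 0.978). In it 2 members rose and 4 fell, or 4 and 4 adjusted over the list alone. PLIN2, a lipid droplet protein, rose 2.34-fold, with a call lost without Delta-2-TGZ replicate 2 (adjusted p = 0.0662), and ANGPTL4 2.02-fold. CPT1A and CPT2 of fatty acid import into mitochondria fell by 0.60 and 0.48, and ACADM and PLIN4 by 0.25 and 0.27 on the log2 scale. The CPT1A call was lost without any control array or without Delta-2-TGZ replicate 2 (adjusted p up to 0.0878), and the CPT2 call without control replicate 1 or 2 or Delta-2-TGZ replicate 1 or 3 (up to 0.056). The calls of ACADM and PLIN4 were lost without any 1 array except Delta-2-TGZ replicate 3 (up to 0.0872 and 0.132). Of 15 aryl hydrocarbon and pregnane X receptor targets, limma called 0, also when adjusted over the list alone, with 1 at an unadjusted p under 0.05 (median and mean 0.03, camera direction down, adjusted p = 0.907). The largest of their differences was that of CYP1B1 (0.34 ± 0.21 SE, adjusted p = 0.327), which ranged from 0.158 to 0.511 over the fits without 1 array.

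Of 20 genes of cholesterol synthesis and uptake 9 rose and 1 fell, or 10 and 1 adjusted over the list alone (median 0.41, adjusted p = 0.000938, but adjusted p = 0.433 with an estimated correlation). STARD4, a sterol carrier, rose 2.81-fold, and the synthesis enzymes HMGCS1 and CYP51A1 2.04-fold and 1.99-fold. TM7SF2 fell (-0.61 ± 0.12 SE), a call lost without control replicate 3 (adjusted p = 0.0559). The list of 22 fatty acid synthesis genes did not shift against other genes (median 0.01, adjusted p = 0.358), with 5 higher and 2 lower, also when adjusted over the list alone. Tested by fry against no change, these genes moved up on balance (adjusted p = 0.0194). ACSS2, ME1 and LPIN1 rose 2.31-fold, 2.18-fold and 2.01-fold, and FADS1 and ACSL1 by 0.79 ± 0.07 and 0.70 ± 0.08 (SE) on the log2 scale. SREBF1, a lipogenic transcription factor, fell 2.08-fold, and ACACB by 0.78 on the log2 scale.

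Of 38 nuclear genes of oxidative phosphorylation 13 fell and 1 rose, or 14 and 1 adjusted over the list alone (median -0.22, adjusted p = 1.17e-05, but adjusted p = 0.249 with an estimated correlation). NDUFB3 of complex I and COX7B of complex IV fell 1.94-fold and 1.86-fold. NDUFB3 had identical values on 2 or 3 arrays of a group, so its variance estimate can be too small. NDUFS4 rose (0.42 ± 0.10 SE), a call lost when probe sets were averaged (adjusted p = 0.0938) and without control replicate 1 or 2 or Delta-2-TGZ replicate 1 or 2 (up to 0.088). Hypoxia and glycolysis genes moved both ways, with 4 of 31 higher and 8 lower, or 4 and 9 adjusted over the list alone. Their median was 0.003 and their mean 0.02, while camera's direction was down (adjusted p = 0.70). VEGFA, a vascular growth factor that is also on the stress list, rose 3.58-fold, EGLN3, an oxygen sensor, fell 2.18-fold and P4HA2 rose 2.02-fold. The other members that rose were ENO2 (0.57 ± 0.15 SE), whose call was lost without any 1 array except Delta-2-TGZ replicate 1 (adjusted p up to 0.129), and KDM3A (0.36 ± 0.07 SE).

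The 38 ribosomal protein genes had a median of -0.13, with members between -0.61 and 0.22 (adjusted p = 0.00103, but adjusted p = 0.457 with an estimated correlation, 0.107 after quantile normalization again and 0.0662 by fry against no change). Limma called RPS23 lower and 0 higher, 0 and 0 adjusted over the list alone, and 12 members had an unadjusted p under 0.05. RPS23 fell by 0.29, a call lost after quantile normalization again (adjusted p = 0.0584), with an intensity trend (adjusted p = 0.0685) and without any 1 array except Delta-2-TGZ replicate 2 (up to 0.134). The 36 genes of ribosome biogenesis did not shift (median -0.04, adjusted p = 0.595), with 3 higher and 5 lower, also when adjusted over the list alone. RRP12, DDX21 and NOP2 rose by 0.52, 0.47 and 0.24, and NHP2, PUS7, NCL, WDR12 and NOLC1 fell by 0.49, 0.42, 0.34, 0.25 and 0.21 on the log2 scale. The DDX21 call was lost without control replicate 2 or 3 or Delta-2-TGZ replicate 2 or 3 (adjusted p up to 0.0827), and the NCL call without any Delta-2-TGZ array (up to 0.0736). The calls of NOP2 and NOLC1 were lost without any 1 array except Delta-2-TGZ replicate 1 (up to 0.143 and 0.135), and that of WDR12 without any except Delta-2-TGZ replicate 2 (up to 0.14). These 3 calls were also lost with dim genes left out (adjusted p = 0.0538, 0.0573 and 0.0521).

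The 29 targets of p53 did not shift as a list (median 0.02, adjusted p = 0.125), with 8 higher and 3 lower, or 10 and 5 adjusted over the list alone, and 6 of them are on other lists. SESN2, GDF15 and GADD45A, stress-induced genes, rose 4.27-fold, 3.57-fold and 3.13-fold. TP53INP1, SUSD6 and CYFIP2 fell by 0.71, 0.54 and 0.51 on the log2 scale, TP53INP1 with a call lost without any 1 array except control replicate 1 (adjusted p up to 0.112) and CYFIP2 without control replicate 3 or any Delta-2-TGZ array (up to 0.0591). Of 27 BCL2 family and death receptor genes 7 rose and 2 fell, also when adjusted over the list alone (median 0.13, adjusted p = 0.0666). PMAIP1, the pro-apoptotic NOXA, rose 3.74-fold, TNFRSF10B, a receptor of TRAIL, 2.83-fold and BCL2L11, the pro-apoptotic BIM, 2.69-fold. BCL2, which opposes apoptosis, fell 2.62-fold (-1.39 ± 0.09 SE). BMF fell by 0.55, a call lost without control replicate 2 or 3 or Delta-2-TGZ replicate 1 or 2 (adjusted p up to 0.0861). Of 28 autophagy and lysosome genes 10 rose and 2 fell, or 12 and 5 adjusted over the list alone (median 0.14, adjusted p = 0.0862). MAP1LC3B, an autophagosome protein, rose 3.45-fold and TFE3 2.64-fold. GLA, a lysosomal hydrolase, fell 2.32-fold and ATP6V1H by 0.46, the latter with a call lost without any 1 array except Delta-2-TGZ replicate 3 (adjusted p up to 0.0869). Against other genes, these 3 lists passed the threshold after quantile normalization again (adjusted p = 0.0379, 0.0283 and 0.0252) and without control replicate 2 (0.0453 for each). The BCL2 family and autophagy lists also did so after median centring (0.0385 and 0.0429). The BCL2 family list did so without control replicate 3 (0.0343) or Delta-2-TGZ replicate 1 (0.0252), and the autophagy list without control replicate 3 (0.0491). Tested by fry against no change, the 3 lists moved up on balance (adjusted p = 0.0147, 0.0227 and 0.0356).

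The interferon list shifted down by camera (median -0.43, adjusted p = 0.0176), but limma called 0 of its 25 members, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05. Adjusted p was 0.711 with an estimated correlation and 0.441 by fry. The list median lay at -0.54, -0.59 and 1.04 on control replicates 1, 2 and 3, and at -0.79, -0.63 and -0.18 on Delta-2-TGZ replicates 1, 2 and 3. Without control replicate 3 the median was -0.01 (adjusted p = 0.592), and the call was also lost without Delta-2-TGZ replicate 1 (adjusted p = 0.0866) or 2 (adjusted p = 0.107). Without both arrays numbered 3 the call held, still down, by camera with the preset correlation. Array weights called 4 members lower, and leaving out both arrays numbered 3 called 3. The largest difference was that of SAMD9 (-1.78 ± 0.82 SE, adjusted p = 0.195), which was called with array weights (adjusted p = 0.0385). It ranged from -2.258 to -0.834 over the fits without 1 array.

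The 21 leukocyte and endothelial markers did not shift (median -0.01, mean 0.05, camera direction up, adjusted p = 0.799), with 2 higher and 0 lower, also when adjusted over the list alone. These were CD68 (0.70 ± 0.15 SE), whose call was lost without control replicate 1 or 2 or Delta-2-TGZ replicate 2 (adjusted p up to 0.0766), and CD8A (0.60 ± 0.08 SE). The 22 mesenchymal and fibroblast markers had a median of 0.05 (adjusted p = 0.181 against other genes, and 0.0119 by fry against no change), with 3 higher and 0 lower, also when adjusted over the list alone. SNAI2, ZEB1 and FN1 rose 1.87-fold, 1.49-fold and 1.48-fold. The SNAI2 call was lost without control replicate 1 or 2 or Delta-2-TGZ replicate 1 or 3 (adjusted p up to 0.123), and the FN1 call without control replicate 1 or 3 or Delta-2-TGZ replicate 2 (up to 0.0565).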

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

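The fit over all probe sets and the divisions of the arrays were planned before their results were seen, and no test in this part was chosen after. The probe sets that name no gene or several genes entered no comparison of genes, and a signal was found in them when the same fit was run over all probe sets. Of 12083 probe sets with no gene listed, 286 rose and 244 fell with Delta-2-TGZ, or 4.39%, with log2 changes between -2.19 and 2.90. Of 1754 probe sets that list several genes, 129 rose and 100 fell, or 13.1%, close to the 14.9% of probe sets with 1 gene. They are given as counts, since the sources used here do not tie them to 1 gene.

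The 6 arrays allow 10 divisions into 3 and 3, too few for a share under 0.05. As many changed genes were found in 1 of the 10, the real division, with 3580, and the highest of the others was 0. At a fold of at least 1.5 the real division gave 1776 genes, again in 1 of 10, and the highest other was 0. For shifted lists by camera with the preset correlation, the real division gave 19, in 1 of 10, and the highest other was 16. The other divisions gave 7 to 16 lists, and each keeps part of the difference between the groups, so these are not numbers under no change. Nor are their gene counts. Arrays of both groups on each side widen the spread, so the counts of 0 lend the real division no support.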

How the results depend on the processing

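Leaving out both arrays numbered 3, and leaving out genes with tied arrays, were chosen after the data were seen. Of 18417 genes 3580 changed, against 5981 with array weights (which gave Delta-2-TGZ replicate 2 a weight of 5.39), 1669 at an adjusted p under 0.01, 1678 without both arrays numbered 3, and 2245 to 3260 without 1 array. The lower count at 0.01 follows from the stricter threshold. Among the fits without 1 array, the count was 3260 and 3256 without Delta-2-TGZ replicate 1 or 3. It was 2267 without Delta-2-TGZ replicate 2 and 2245 to 2322 without a control array. The number of arrays alone does not give this split. Its cause, and that of the higher count with array weights, were not tested. The other alternatives gave 3495 to 3863 genes. Of the 1776 genes changed at least 1.5-fold, 608 reached 2-fold, and the other alternatives gave 1217 to 1879. Of the 19 lists called, 4 were called with an estimated correlation, and other alternatives called 18 to 22. Members that vary together do not account for each lost call. The cytosolic heat shock and proteasome lists had estimated correlations of 0.006 and -0.007, below the preset 0.01. Their calls were lost all the same (camera adjusted p = 0.106 and 0.0937). That setting also uses the 4 residual degrees of freedom. A call lost in it does not by itself show that members vary together. The share of calls that were higher was 49.4%, and it ranged from 43.1% with median centring to 57.6% without both arrays numbered 3, with 55% without control replicate 3.

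The replicate block gave 3863 changed genes, 1879 of at least 1.5-fold and 19 lists, and it called 7 interferon members lower, among them SAMD9 (-1.78, adjusted p = 0.0284), and CYP1B1 higher (0.34, adjusted p = 0.0363). The deviations of same-numbered arrays from their group means correlated at 0.043, 0.253 and 0.326, and 4 of 6 arrays correlated best with their own number. These values leave open whether the numbers pair the arrays. The labels do not say that they do, so the main fit had no block. Over all alternatives, 175 genes, those of the rule for named genes, of short counts and of added families, gave the same call in 2343 cases, lost it in 273 and gained it in 3, with no reversal. Of the 170 that were called, 122 kept the call in each fit without 1 array, and 56 lost it without both arrays numbered 3, where 2 arrays per group remain. The 29 lists gave the same call in 483 cases, lost it in 23 and gained it in 16. Signal over background was not analysed here, so the levels of dim genes are uncertain, such as those with tied arrays, at a median level of 5.54. Lost calls were not confined to dim genes. CLDN3, at a control level of 11.8, lost its call in 10 of 15 alternatives.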

Other observations

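The gene families in the first paragraphs and the tests of the 3 patterns that follow were chosen after the values were seen. For the first 4 families, chosen with their members' changes in view, no test as a group is given. Their counts adjusted over the list alone depend on that choice too and serve as description only. Of 8 measured ligands of the natural killer receptor NKG2D, 5 rose with Delta-2-TGZ and 0 fell, or 6 and 1 adjusted over the list alone (median log2 change 0.46). After ULBP1 (3.31 ± 0.08 SE), RAET1L rose by 2.15 ± 0.16, ULBP2 by 1.65 ± 0.15, ULBP3 by 0.60 ± 0.15 and RAET1G by 0.33 ± 0.06 (SE, n = 3 per group). The ULBP3 call was lost without any 1 array except control replicate 1 (adjusted p up to 0.105), and the RAET1G call without both arrays numbered 3 (adjusted p = 0.059). RAET1G had identical values on control replicates 2 and 3, so its error can be too small. MICA and MICB, of the same receptor's ligands, differed by 0.32 (adjusted p = 0.0669) and -0.24 (adjusted p = 0.125). The ULBP and RAET1 genes are close relatives, and their probe sets can share signal.

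Of 10 ligands of the EGF receptor family 3 rose and 0 fell, or 4 and 0 adjusted over the list alone (median 0.20). After HBEGF (3.69 ± 0.22 SE), BTC, betacellulin, rose by 0.99 ± 0.18, with a call lost without Delta-2-TGZ replicate 2 (adjusted p = 0.0542), and EPGN by 0.58 ± 0.07 from a low level of 3.41, not separated from background. Of 23 claudins 3 rose and 1 fell, also when adjusted over the list alone (median 0.01). These were CLDN1 (4.26), CLDN12 (0.89), CLDN7 (0.25) and CLDN3 (-0.24), CLDN12 with a call lost without both arrays numbered 3 (adjusted p = 0.0585) and the last 2 with calls lost without any 1 array except Delta-2-TGZ replicate 1 (adjusted p up to 0.0958 and 0.133). Of 28 tubulins and tubulin complex genes 5 rose and 4 fell, or 6 and 5 adjusted over the list alone. TUBE1, epsilon tubulin, rose by 2.19 ± 0.08 (SE), TUBB2A by 1.17, TUBA4A by 0.70, TUBB6 by 0.64 and TUBA1A by 0.36, and TUBGCP5, TUBD1, TUBGCP2 and TUBBP5 fell by 0.64, 0.53, 0.44 and 0.43. The TUBA1A call was lost without any 1 array except Delta-2-TGZ replicate 1 (adjusted p up to 0.0984), that of TUBGCP2 without any except Delta-2-TGZ replicate 2 (up to 0.0991), that of TUBBP5 without control replicate 1 or 3 or Delta-2-TGZ replicate 2 (up to 0.0613), and that of TUBA4A without control replicate 1 (0.0523). Of 192 small nucleolar and Cajal body RNAs 5 rose and 8 fell (median -0.07, camera adjusted p = 0.0644 over 7 added families). SNORD14E, SNORD75, SNORD59A, SNORA75 and SNORA70G rose by 1.43, 1.25, 0.98, 0.66 and 0.32. The SNORA70G call was lost without both arrays numbered 3 (adjusted p = 0.0879). The SNORA75 call was lost without any 1 array except Delta-2-TGZ replicate 2 (adjusted p up to 0.147). It was also lost with array weights (0.35, adjusted p = 0.1125). The SNORD59A call was lost without control replicate 1 or 2 (up to 0.0856), and that of SNORD75 without control replicate 1 or 2 or Delta-2-TGZ replicate 2 or 3 (up to 0.0828). Adjusted over the list alone limma called 0 of the 192 RNAs, with 38 at an unadjusted p under 0.05. Of 439 zinc finger genes 40 rose and 42 fell, also when adjusted over the list alone (adjusted p = 0.892). Among 341 olfactory receptors, taken as genes with little expression in these cells, OR4M2 rose by 0.35, a call lost without control replicate 1 or 3 or Delta-2-TGZ replicate 2 (adjusted p up to 0.056), and 0 fell (adjusted p = 0.584 for the list). Of these receptors limma called 0 adjusted over the list alone, and 7 had an unadjusted p under 0.05.

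All 25 interferon genes were higher on control replicate 3 than on both other controls, by a median of 1.56 on the log2 scale. Array-wide scaling left in the deposited values is argued against, since the medians of the control arrays lay at 6.58, 6.54 and 6.56. The gap stayed at 1.501 after quantile normalization was applied again. That step could change little, because RMA had already made the distributions of probe intensities equal. RNA from blood, endothelial or stromal cells is also argued against: the median gap of 43 markers, of which 10 lay above a level of 7 in the other controls, was -0.007 with an upper quartile of 0.07, and COL1A1 (7.65), VIM (5.59), LYZ (4.39) and PTPRC (3.69) on that array differed by -0.22, -0.06, 0.04 and 0.04, genes picked after their values were seen. A handling or culture difference shared by the arrays numbered 3 stays open as a candidate explanation, since Delta-2-TGZ replicate 3 lay 0.448 above the higher of the other treated arrays, but with 1 array per number and group it cannot be told apart from a difference of single cultures. No biological explanation named by the groups was tested, because the pattern lies within the control group.

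Of 42 mitosis genes 41 were lower on Delta-2-TGZ replicate 3 than on both other treated arrays. Array-wide scaling left in the deposited values is argued against, since the medians of the treated arrays lay between 6.57 and 6.63. The range of the list median over the treated arrays was 1.32 after quantile normalization was applied again and 1.35 before. That step could change little after RMA. An evenly stronger response on replicate 3 is argued against for the mitosis list. Its median lay at -1.38 there, against -0.03 and -0.42 on replicates 1 and 2. The ATF4 and CHOP members lay only 0.014 higher there in the median, with an interquartile range of 0.358 over members. The slope over all changed genes was 1.04, though calls favour genes with little spread between arrays. A response stronger in some lists alone is not covered, since the G1/S and estrogen receptor lists had median gaps of -0.465 and -0.256. A later point of the same cell cycle change stays open. Of 42 G1/S genes 33 were lower on replicate 3 than on both others, which the single time point cannot settle. The gap between the G1/S and mitosis medians was -0.58 ± 0.38 (SD, n = 3) with Delta-2-TGZ and 0.005 ± 0.028 in control, with p = 0.10 in an exact two-sided permutation test, the smallest that 3 against 3 allows.

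PPARG mRNA rose while the list of PPAR targets did not shift. If the compound activated these targets, the members measured above a log2 level of 7 would rise, and the median over these 11 was -0.117. In them 2 rose and 3 fell, so activation of all of them is not seen, but a median over members that go both ways does not decide about single genes such as PLIN2. Whether PPARγ protein or its activity changed was not analysed here, and the question stays open.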
